A study of Caenorhabditis elegans with 2 samples.

How the data were processed

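The series holds anti-GFP ChIP-seq of whole late embryos of a C. elegans strain carrying FAX-1 fused to GFP, with 2 biological replicates in 1 group. Chromatin was fragmented by sonication, per the labels. The authors deposited peak lists on the ce11 and ce10 builds: a loosely called list for each replicate, a loosely called list for the pooled replicates, and a list filtered for reproducibility between replicates by the irreproducible discovery rate (IDR). The pooled calling also took a control file, per the file headers and metadata texts. The aligner, the peak caller, the IDR threshold and the read depth are not given in the sources used here. Reads, coverage tracks and the control were not analysed.

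The deposited signal value of each peak is taken here, from the column's place in the format, as the enrichment score of the authors' peak caller, which is not named. Its floor differs between lists, so signals were compared across lists by rank. The deposited −log10 q value of each peak ties at its maximum for 78.8% of the final ce11 peaks and was not used for ranking. The files name the columns by the standard order of the format, and 0 columns could not be placed. Every row of the final list was a row of the pooled list, and the final list was exactly its strongest 830 rows on ce11 and strongest 999 on ce10. Peak width was 436 bp for 77.0% of final ce11 rows.

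Analyses used the ce11 lists. Chromosome names and lengths of that build were compared with the WBcel235 reference sequence, which they fit, and genes came from Ensembl release 115, with 19985 protein-coding genes. Names of tRNA and mitochondrial genes came from the RefSeq table of the same assembly, matched by position. No ce10 sequence was among the references used here, so the ce10 lists were compared by number, chromosome and signal only. No position was converted. Overlapping rows of a list were merged and represented by the row with the highest signal. Weaker candidates were the merged pooled regions that overlapped no final region. The 13 mitochondrial regions were kept in the comparison of replicates and left out of tests on genes, chromosomes and sequence.

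The design and the alternatives were fixed before the data were examined, except where the text says otherwise. Replicates were compared by the share of the 830 strongest peaks that overlapped by at least 1 bp, with 1000 random placements, and by Spearman correlation with 1000 bootstrap draws. Summits were tested against weaker candidates with two-sided Fisher's exact tests, and against 10000 sets of random positions on the same chromosomes. A summit was near a gene start within 500 bp and was assigned to the nearest protein-coding 5′ end within 5000 bp. Summits within 500 bp of a tRNA gene, or of an snRNA, snoRNA or rRNA gene, were counted for those classes. There were 22 gene lists: fax-1 genetics, command interneuron, neuropeptides, pan-neuronal, axon guidance, neurotransmitter receptors, homeobox, nuclear receptors, bHLH, body muscle, pharynx, intestine, epidermis, glia, germline, cuticle collagens, ribosomal proteins, proteasome, histones, chemoreceptors, tRNA genes and small RNA genes. Of their names, 2 matched no symbol in the annotation and were left out: opt-3 of the fax-1 genetics list and efn-1 of the axon guidance list. Sequences were searched on both strands in 151-bp windows centred on the summit and on a point 500 bp to the right, and compared by exact McNemar tests. P values were adjusted by Benjamini-Hochberg within each family: 22 gene lists, 6 chromosomes, 8 fixed sequences and 2080 6-mers. In the test over genes and without the regions at tRNA and small RNA genes, those 2 lists were not in the family. The p values for X, the only chromosome named in the fixed design, are given unadjusted. The threshold was 0.05.

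The named genes are fax-1, the genes nearest to the 20 strongest final regions, and the 4 members with the strongest peak of each list that passed its test. All members of the fax-1 genetics list that were matched in the annotation are also named. Other list members with a final region were named after their values were seen.

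The alternatives were other distances and windows, other definitions of overlap, the stronger 50% of the final list, each replicate's own 830 strongest peaks in place of the final list, random positions, a test over genes and the ce10 lists. Alternatives without the regions at tRNA and small RNA genes, and the correlation on nuclear chromosomes only, were added after seeing the data.

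The methods were tested on simulated data. With 10 6-mers planted in 783 genomic stretches, the 6-mer search recovered 10 and called 32 others, 28 of which share 5 bases with a planted one. Those stretches lay at random positions, so calls driven by the base composition of real summits were not measured. In 20 simulated sets of 783 regions, with 40 regions of each of 2 lists added, the list test recovered 40 of 40 planted lists. It made 4 other calls. Its power for lists with few regions was not measured. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.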

Results

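Binding of FAX-1, a nuclear hormone receptor that guides axons and sets the identity of interneurons, was mapped by ChIP-seq in late embryos of C. elegans. The worms carried a transgene that makes FAX-1 fused to GFP at its C-terminus, and chromatin from whole animals was precipitated with an antibody against GFP, 4 h after synchronization. The group held 2 biological replicates, and no other stage, factor or untagged strain was available for comparison. On the ce11 build, replicate 1 had 15446 candidate peaks and replicate 2 had 18555, both called loosely so that their agreement could be scored. Pooling the replicates gave 13841 candidates, of which the reproducibility filter of the authors kept 830. Merging overlapping peaks left 796 distinct final regions, 783 of them on the nuclear chromosomes and 13 on mitochondrial DNA. Read depth is not given in the sources used here. All final peaks were the strongest of the pooled candidates: 830 candidates had a signal at or above the lowest final value of 98.3, taken from the signal column and called the peak caller's units here because its scale is not stated. Comparisons of the final regions with the other candidates, called weaker candidates here, are therefore comparisons of strong with weak or no enrichment. The pooled list is labelled as holding peaks and background, and its −log10 q values go down to 0.0176. Intervals are 95% Wilson intervals and cover counting error only.

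The strongest region lay in the intergenic stretch of chromosome III at 8043695 to 8044255, with a signal of 2532 and its summit 531 bp upstream of K12H4.5. It ranked 1 in both replicates, with signals of 1627 and 910.8. The next nuclear region, at III 3499837 to 3500287, had a signal of 1220 and lay in an intron of M01F1.8, closest to the start of M01F1.9. Among the 20 strongest final regions, 11 were nuclear and 9 were mitochondrial. The other nuclear ones were nearest to the starts of hrg-5 (signal 748.8), ears-2 (672.5), F55C5.17 (668.5), eel-1 (659.0), W03C9.1 (620.7), vps-51 (615.8), Y41D4A.4 (553.2), sre-23 (551.6) and pxn-1 (551.3). For pxn-1, a peroxidasin of the extracellular matrix, the summit lay within an intron 5679 bp from the gene's start. The summits near ears-2, which encodes an aminoacyl-tRNA synthetase, vps-51, a subunit of a tethering complex for endosomal vesicles, and Y41D4A.4 lay 34, 178 and 240 bp upstream of the gene starts. The mitochondrial summits fell in ND5, COX1 (2 regions), COX3, CYTB, ND2, ND4, ND1 and a ribosomal RNA gene. Mitochondrial regions were kept in the comparison of replicates and left out of the tests on genes, chromosomes and sequence.

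Strong peaks recurred between the replicates. Of the 830 strongest peaks of replicate 1, 611 (73.6%, interval 70.5 to 76.5%) overlapped one of the 830 strongest of replicate 2 by at least 1 bp. Random placement of the same peaks within their chromosomes gave 2.12% on average and at most 3.37% in 1000 draws. The final list held exactly the strongest candidates of these pooled replicates, so its overlap with them was largely set by that choice. Every final region overlapped a candidate of replicate 1, and 795 of 796 one of replicate 2. Across those 795 regions, mitochondrial ones included, the signals of the replicates had a Spearman correlation of 0.70 (bootstrap 95% interval 0.65 to 0.74), against 0.55 across the 6345 pooled regions found in both replicates and 0.69 across 782 nuclear final regions. These correlations are across genomic regions, which are not independent replicates.

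**Figure D1:**
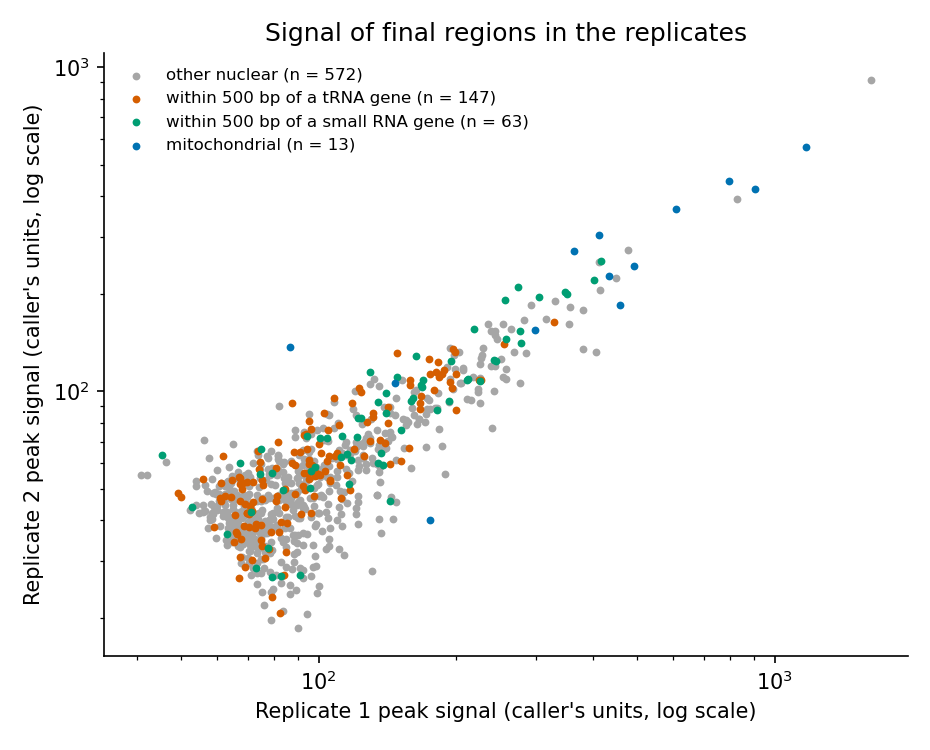
Peak signal of each final region in replicate 1 (horizontal, log scale) and replicate 2 (vertical, log scale), in the peak caller's units; each point is a region, coloured by the RNA gene near its summit. Mitochondrial regions and regions at tRNA and small RNA genes largely follow the same diagonal as the other regions. Exceptions include the mitochondrial regions at 1713 to 1890 (86.6 in replicate 1, 137.3 in replicate 2) and 5111 to 5324 (175.9 and 40.2). The topmost point is the region upstream of K12H4.5.

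No peak marked the fax-1 gene itself (WBGene00001400, X 3196064 to 3199349). The final list had no summit in the gene or within 5000 bp of it, and neither did the pooled candidates or either replicate. The nearest final summit was 68196 bp away and the nearest pooled candidate 16621 bp away, with a signal of 32.5. Genes tied to fax-1 by genetics or by their expression in the neurons it specifies were also without final regions. These are flp-1, a neuropeptide gene of the AVK interneurons, ncs-1, a neuronal calcium sensor, the NMDA receptor genes nmr-1 and nmr-2, and the homeobox gene unc-42. Weaker candidates were assigned to flp-1 (1 region, signal 37.4) and to unc-42 (2 regions, highest signal 82.6), while ncs-1, nmr-1 and nmr-2 had none. The stronger unc-42 candidate differed between the replicates. In replicate 2 its peak (V 9769340 to 9769775, summit 167 bp upstream of the gene start, signal 46.7) ranked 535, among the 830 strongest, and in replicate 1 the overlapping peak ranked 3500. With the strongest peaks of replicate 2 in place of the final list, this 1 region gave the fax-1 genetics and command interneuron lists odds ratios of 7.64 and 2.54 (Fisher's exact tests, adjusted p = 0.477 and 0.79).

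Strong peaks lay at short non-coding RNA genes more often than weaker candidates did. Of the 783 nuclear final regions, 147 (18.8%, interval 16.2 to 21.7%) had their summit within 500 bp of a tRNA gene, against 168 of 11908 weaker candidates (1.41%). The odds ratio was 16.2 (two-sided Fisher's exact test, adjusted p = 7.88e-94 over 22 gene lists). The summit lay inside the tRNA gene in 88 of the 147 regions and within 100 bp of it in 144. Counted from the genes, 168 of 612 nuclear tRNA genes (27.5%, interval 24.1 to 31.1%) had a final summit within 500 bp. The strongest were C04A11.t1 (X 13665555 to 13665673, signal 492.7), F15G9.t1 (X 9743589 to 9743660, 393.4), C02B4.t2 (X 12665228 to 12665311, 338.4) and C42D8.t1 (X 5085622 to 5085695, 332.3).

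Genes annotated as small nucleolar or small nuclear RNAs were also marked. A summit lay within 500 bp of such a gene in 63 final regions (8.05%) and in 0.941% of weaker candidates, an odds ratio of 9.22 (Fisher's exact test, adjusted p = 2.63e-31). Of these regions, 55 were at snoRNA genes, which guide the chemical modification of other RNAs, and 8 at genes annotated as snRNA, among them the spliced-leader genes sls-2.1, sls-2.2 and sls-2.4, whose RNA is joined to the 5′ ends of messenger RNAs by trans-splicing. None was at an rRNA gene. Unlike at tRNA genes, few summits were inside the gene: 3 of 63, although 55 lay within 100 bp of it. The strongest were the snoRNA genes C51F7.4 (V 12303599 to 12303693, signal 668.5), which sits in an intron of frm-7, W03C9.9 (II, 620.7), ZK265.10 (I, 551.6) and ZK994.7 (V, 551.3). These same regions are the ones listed above by their nearest protein-coding genes F55C5.17, W03C9.1, sre-23 and pxn-1. The median signal was 160.9 over the 210 regions at either class of RNA gene and 133.6 over the other 573.

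The strong peaks concentrated upstream of protein-coding genes. Summits lay within 500 bp of the 5′ end of a protein-coding gene in 402 of 783 final regions (51.3%, interval 47.8 to 54.8%) and in 3052 of 11908 weaker candidates (25.6%). The odds ratio was 3.06 (two-sided Fisher's exact test, p = 1.99e-49). Random positions on the same chromosomes gave 18.4% on average, with a central 95% range of 15.8 to 21.1%. The median distance from summit to gene start was 446 bp for final regions and 1401 bp for weaker candidates, and 69.3% of final summits lay upstream of the gene, against 46.7% of the others. Away from gene starts, 167 final summits were in introns, 202 between genes, 7 in coding exons, 3 in 5′ UTRs and 2 in 3′ UTRs. Coding exons held 0.894% of final summits, against 1668 of the 11908 weaker ones.

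**Figure D2:**
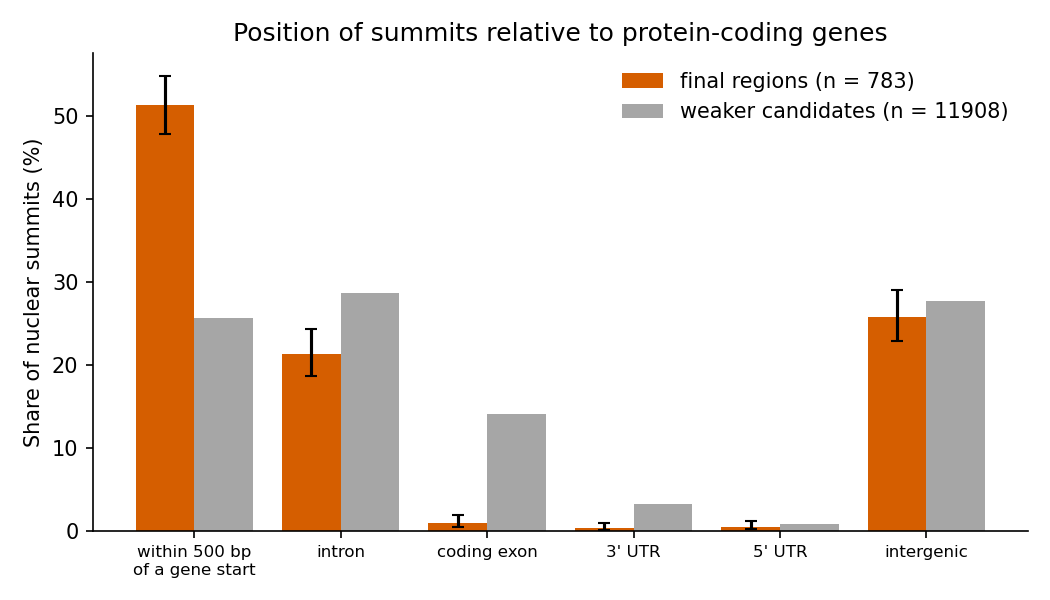
Share of nuclear summits (vertical, %) by position relative to protein-coding genes, for the 783 final regions and the 11908 weaker candidates; bars on the final regions are 95% Wilson intervals. Final summits sit near gene starts in 51.3% of regions, against 25.6%, and are rare in coding exons.

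The X chromosome carried 150 final regions (19.2%, interval 16.6 to 22.1%), against 17.7% of the weaker candidates and 17.7% of the nuclear genome's length. Neither difference passed its test (Fisher's exact test, p = 0.288; exact binomial test against length, p = 0.281). Of the 150 regions on X, 73 were at tRNA genes, 77 at neither class of RNA gene, and 0 at the 36 small RNA genes there. Chromosome X holds 276 of the 612 nuclear tRNA genes (45.1%) and had 49.7% of the final regions at tRNA genes. Without the regions at tRNA and small RNA genes, X held 13.4% of the final regions and 17.5% of the weaker candidates (Fisher's exact test, p = 0.0109). That comparison was chosen after seeing the data, and its p is not adjusted for the 6 chromosomes. The fixed design named X only, and chromosomes III and V are given because they passed relative to length when all 6 were examined. Chromosome III had more final regions than its share of length (147, 18.8% against 13.7%, exact binomial test, adjusted p = 0.000284 over 6 chromosomes). Chromosome V had fewer (109, 13.9% against 20.9%; exact binomial test, adjusted p = 3.76e-06). Against the weaker candidates, neither passed (Fisher's exact tests, adjusted p = 0.49 and 0.576).

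**Figure D3:**
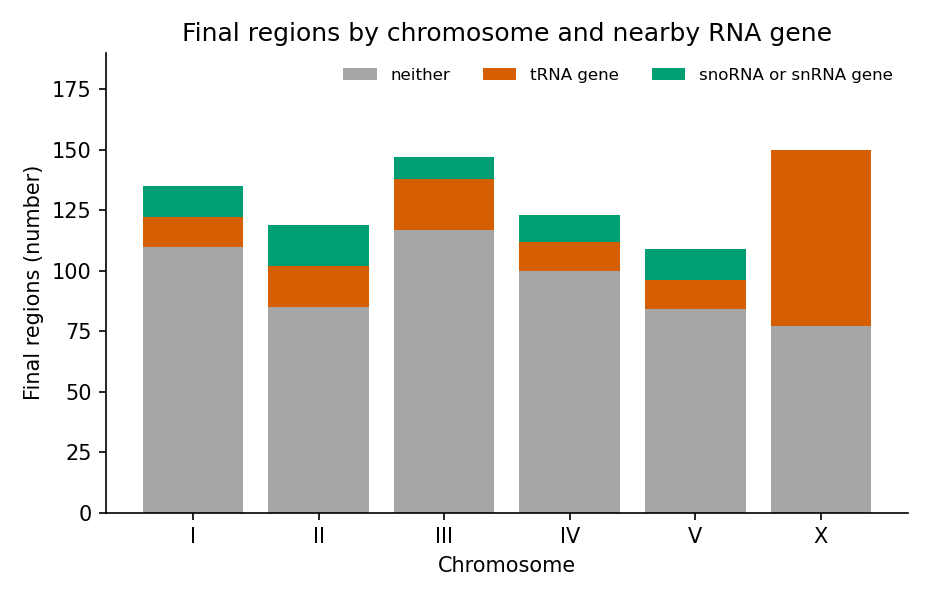
Number of final regions (vertical) on each nuclear chromosome (horizontal), split by whether the summit lay within 500 bp of a tRNA gene, of a snoRNA or snRNA gene, or of neither. On X, 73 of 150 regions are at tRNA genes and none at a snoRNA or snRNA gene.

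No list of nervous system genes passed as over-represented among the strong peaks. Each final region was assigned to the nearest protein-coding gene start within 5000 bp. The 141 neuropeptide genes received 4 regions (nlp-4, nlp-76, ins-13 and flp-23), 0.511% of final regions and 0.529% of weaker candidates. The summits of all these regions were within 500 bp of a tRNA or small RNA gene. Pan-neuronal genes received 2 regions (unc-31 and syd-2), axon guidance genes 3 (lin-17, unc-76 and sax-7), neurotransmitter receptors 1 (lgc-21) and command interneuron genes 0. For these lists the adjusted p of Fisher's exact test was between 0.332 and 1. Counted over genes, 10% of pan-neuronal and 8.11% of axon guidance genes had a final region, against 3.52% of all genes. Neither passed (Fisher's exact tests, adjusted p = 0.389 for both). Neuropeptide (2.84%), neurotransmitter receptor (0.794%) and command interneuron genes (0%) were below that share. With 0 to 4 regions per list, these tests cannot exclude enrichment.

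Among transcription factors, the 97 homeobox genes received 0 final regions, which allows a share of up to 0.488%, and 93 weaker candidates (0.781%; Fisher's exact test, adjusted p = 0.031). That difference passed again with assignment within 10000 bp (Fisher's exact test, adjusted p = 0.0141). It did not pass under the other alternatives, among them either replicate's own strongest peaks (adjusted p = 0.203 and 0.235, Fisher's exact test) and random positions (Monte Carlo test, adjusted p = 0.0774). The 274 nuclear receptor genes received 5 final regions (nhr-255, nhr-41, nhr-1, nhr-48 and nhr-20), 0.639% against 1.08%, and bHLH genes received 1, at lin-32. The regions of nhr-255, nhr-41 and lin-32 had their summits inside tRNA genes, and that of lgc-21 lay 7 bp from one. Neither the nuclear receptor nor the bHLH list passed against the weaker candidates (Fisher's exact test, adjusted p = 0.776 and 1).

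Among the remaining lists, ribosomal protein genes received 8 final regions at 7 genes, including rps-24, rpl-3, rpl-15 and rpl-12, which was 1.02% against 0.445% (odds ratio 2.31; Fisher's exact test, adjusted p = 0.235). With regions at tRNA and small RNA genes left out, the odds ratio was 3.28 (Fisher's exact test, adjusted p = 0.0362). The list also passed in the 391 strongest regions (odds ratio 4.08, Fisher's exact test, adjusted p = 0.0206) and against random positions, which gave 1.59 regions on average (Monte Carlo test, adjusted p = 0.0055). It did not pass with either replicate's own strongest peaks (adjusted p = 0.0582 and 0.235), within 1000 or 10000 bp (0.0547 and 0.27) or over genes (0.17; all Fisher's exact tests). The 1353 chemoreceptor genes received 8 regions, 1.02% against 2.17% (odds ratio 0.466; Fisher's exact test, adjusted p = 0.153). With regions at tRNA and small RNA genes left out they received 3 (odds ratio 0.239; Fisher's exact test, adjusted p = 0.0362). They were also below random positions, which gave 30.2 regions on average (permutation test, adjusted p = 0.00147). The same direction passed in a test over genes and with the strongest peaks of replicate 2 in place of the final list (Fisher's exact tests, adjusted p = 8.38e-12 and 0.0313). It did not pass with those of replicate 1 (adjusted p = 0.235), in the 391 strongest regions (0.902), or within 1000 or 10000 bp (0.893 and 0.0903; all Fisher's exact tests). The cuticle collagens received 5, all at summits within 500 bp of a tRNA or small RNA gene. Leaving those regions out therefore fixed the collagen count at 0 of 573, against 1.17% of weaker candidates (Fisher's exact test, adjusted p = 0.0362). That p cannot show depletion, and random positions gave 4.97 collagen regions on average, against the 5 received. Body muscle genes received 4 (unc-97, unc-112, unc-54 and unc-60). Over genes, 13.8% of that list had a final region, against 3.52% of all genes (Fisher's exact test, adjusted p = 0.17). Its odds ratio was 0 in the 391 strongest regions and 0.381 with the strongest peaks of replicate 2, and it passed under no alternative. The proteasome and histone lists received 1 each, at pbs-3 and his-67. Markers of the pharynx, intestine, epidermis, glia and germline received 0. Over all final regions, the adjusted p for collagens, muscle, proteasome, histones and these markers was between 0.695 and 1 (Fisher's exact tests).

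Receptors of the FAX-1 class recognise a short DNA element, AAGTCA, so its frequency at the summits was compared with that in flanking sequence. The sequence occurred on either strand within 75 bp of the summit in 26 of 783 final regions (3.32%, interval 2.28 to 4.82%). In windows of the same size centred 500 bp to the right it occurred in 53 (6.77%, interval 5.21 to 8.75%). The element was thus less frequent at the summit than beside it (exact McNemar test, two-sided, adjusted p = 0.0056 over 8 sequences), and in the 391 strongest nuclear regions alone the difference did not pass (3.58% against 6.65%, exact McNemar test, p = 0.0807). Weaker candidates had it at 5.17% of summits. The related AGGTCA did not differ between summit and flank (4.98% against 4.60%; exact McNemar test, adjusted p = 0.929), nor did the extended form AAAGTCA (1.53% against 2.94%; exact McNemar test, adjusted p = 0.143).

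Of the sequences bound by other classes of factor, GAGAGA was more frequent at the summits, in 24.9% of windows against 8.68% (exact McNemar test, adjusted p = 3.66e-16). The GATA-type sequence TGATAA and the homeodomain-type TAATTA were less frequent there. They were in 4.47% against 12.9% and 4.34% against 8.17% of windows (exact McNemar tests, adjusted p = 1.22e-08 and 0.0056). In the open search described below, 35 of the 36 sequences with 0 G or C bases, as in TAATTA, were less frequent at the summits. With 1 such base, as in TGATAA, 143 of 192 were. In both classes 0 were more frequent at the summits. Scarcity of these 2 sequences beyond that of their classes was not tested, so depletion of GATA or homeodomain sites is not shown. CAGCTG and TGACTCA did not differ (exact McNemar tests, adjusted p = 0.159 and 1).

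**Figure D4:**
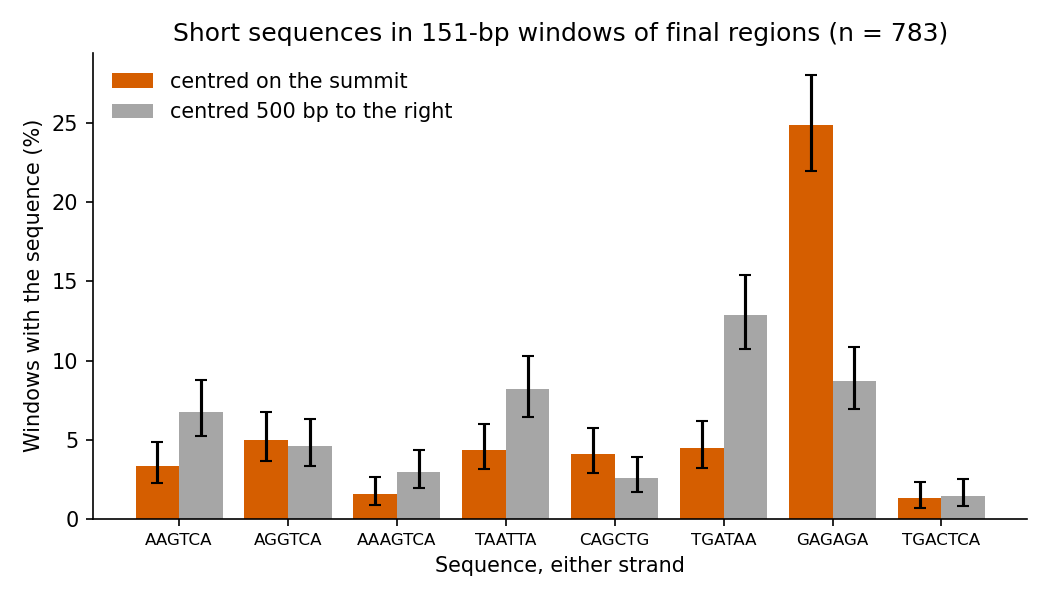
Share of windows (vertical, %) that contain each sequence on either strand (horizontal), for windows centred on the summit and windows centred 500 bp to the right, over the 783 nuclear final regions; bars are 95% Wilson intervals. GAGAGA stands out at the summits (24.9%), and AAGTCA is at 3.32% there against 6.77% beside them.

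In an open search, 900 of the 2080 distinct 6-mers differed between summit and flank, 476 of them more frequent at the summit (exact McNemar tests, Benjamini-Hochberg adjusted). The leading ones were ACGCGC (15.8% against 1.92%, adjusted p = 4.67e-20, exact McNemar test), CGCGCA (16.7% against 2.55%) and GAGCGC (15.2% against 1.92%). Of the 612 nuclear tRNA genes, 472 had identical copies, so windows at them can repeat the same sequence. The tests nevertheless count each window as independent. Summit sequence was richer in G and C: the mean GC content was 46.7% in summit windows, 36.8% in the right flank and 40.4% at the summits of weaker candidates. Of the 476, 465 contained 3 or more G or C bases, and of the 424 that were less frequent at the summit, 349 contained 2 or fewer.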

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

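Across the alternatives, the share of final summits near gene starts stayed above its background and passed in each of 7 settings. It ranged from 35.0% within 250 bp to 63.2% without regions at tRNA and small RNA genes. It was 47.9 to 50.8% with either replicate's own strongest peaks in place of the final list. In that setting the weaker candidates still came from the list pooled over both replicates. The tRNA and small RNA lists passed in the stronger regions, with either replicate's own strongest peaks and against random positions. The distance to a protein-coding gene start does not enter these lists. Replicate overlap was 65.1% when 50% of both peaks had to overlap reciprocally, 69.2% for summits within 100 bp, 80.7% for the strongest 415 peaks and 64.5% for the strongest 1660, so it fell with a stricter overlap and a longer list. The signal correlation was 0.75 in the 398 strongest regions and 0.55 over the 6345 of 12704 pooled regions found in both replicates. With reciprocal overlap it was 0.61, over 694 of 796 final regions. X held 17.4% of the 391 strongest nuclear regions and 13.4% without the RNA gene regions, both below the weaker candidates rather than above; the former difference did not pass (Fisher's exact test, p = 0.946), and the cause of the latter, with RNA gene regions removed from both sides, was not tested. AAGTCA was at 3.58% of the 391 strongest summits, and with fewer regions the difference no longer passed. A test over genes called 1 list, the chemoreceptors, against 3; tRNA and small RNA lists cannot enter it. Homeobox genes, ribosomal proteins, chemoreceptors and collagens passed under some settings only. For collagens, the setting without RNA gene regions had itself removed all their final regions. The 391 strongest regions gave 285 6-mers that were more frequent at summits, against 476, with fewer regions to test. Without the regions at tRNA and small RNA genes, the remaining 573 regions gave 323. In that setting 577 of the 900 6-mers that differed in either direction passed again. The ce10 list gave 959 regions. Depth and control signal are unknown, so neither their effect nor that of the IDR threshold could be tested.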

Other observations

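Outside tRNA and small RNA genes, the 573 remaining final regions shared some longer sequences, of which examples were chosen after seeing the counts. Genes annotated as ncRNA are not in those classes, so regions with summits in rpr-1, srpr-2.2 and mrpr-1 were among those remaining. The most frequent 12-mer, AGAGGAGTACAC, occurred within 75 bp of the summit in 23 of them and in 1 of their right flanks, and the nuclear genome holds 150 copies. Several 12-mers that overlap it followed, at 20 or 21 summits, then repeats of AG at 17 to 19. A sequence unrelated to these, ACGAAAAGGGGA, occurred at 16 summits and 0 flanks, with 373 copies in the nuclear genome. In the same 573 regions, GAGAGA remained at 26.0% of summits against 8.90% of flanks, and GAGCGC led the 6-mers at 16.9% against 1.57%. AAGTCA was at 2.62% against 6.63%.

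The tests reported next were fixed before their results were seen, except the one on tRNA genes that share no 30-base stretch and the decision rules of the tests on tRNA genes of unique sequence and on dilution of AAGTCA, which were tightened afterwards. The mitochondrial genome gave 13 final regions, which the tests on genes, chromosomes and sequence leave out and for which no control peak list was available. All 13 mitochondrial regions among the pooled candidates entered the final list, with a median signal of 660.6 against 138.97 for nuclear final regions, and they covered 35.8% of the 13794 bp. That coverage, tested first, went with many copies of mitochondrial DNA, but the number of regions, already known, largely fixed it, so a test on summit positions replaced it. If they reflected many copies of mitochondrial DNA with no local structure, their summits would fall at unrelated places in the replicates. Of the 14 mitochondrial summits of replicate 1, 11 lay within 100 bp of one of replicate 2, against 2.69 on average and a central 95% range of 0 to 6 in random placements (permutation p = 0.0002, the smallest that 10000 placements can give), which argues against that explanation. Uneven recovery or mapping of abundant mitochondrial DNA, repeated in both replicates, stays open, as it was not tested, and no biological explanation was tested.

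The strong peaks at tRNA genes may reflect FAX-1, chromatin that is recovered readily at heavily transcribed genes, or reads that fit several copies. Base composition does not account for them: among weaker candidates matched to the final regions on GC content, 2.02% were near a tRNA gene (interval 1.66 to 2.47%), against 18.8%. Reads shared between identical genes stay open: tRNA genes of unique sequence had a final region in 16.4% of cases (23 of 140, interval 11.2 to 23.4%) and genes with identical copies in 30.7%, both above the 0.884% at random positions, and the share met the bound set in advance, but its interval spans that bound. The requirement that the interval clear it was added after the value was seen. Only 20 tRNA genes shared no 30-base stretch with another place; 1 of them had a final region, with a lower bound of 0.888%, which decides nothing. Recovery of transcribed chromatin without FAX-1 needs an untagged strain or the control and was not tested.

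The scarcity of AAGTCA at summits is in line with the GC-rich sequence there: its summit-to-flank ratio of 0.491 lay within the central 95% range of 0.293 to 1.56 of the 491 other 6-mers with 2 G or C bases, whose median was 0.739. Dilution by the weaker of the final regions stays open. AAGTCA was at 3.58% of the 391 strongest summits and 3.06% of the other 392, a difference of 0.519 percentage points (95% interval -1.99 to 3.03; Fisher's exact test, p = 0.696). That interval is wide beside the share itself, and the bound set in advance exceeded the whole share, so it could exclude nothing. Binding through partner proteins or another sequence was not tested.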
